A study of Lilium maculatum with 15 samples.

How the data were processed

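The series holds 15 samples of the lily Lilium maculatum. Small RNA, messenger RNA and full-length transcripts were sequenced from leaf and from anthers sorted by length. The values analysed come from the 6 small RNA libraries: 1 from leaf and 1 each from anthers of 4, 5, 6, 8 and 10 mm. The other 9 samples, of messenger RNA and full-length transcripts, were not analysed here.

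Per the labels' protocols, total RNA was run on a gel and small RNAs of 20 to 30 nt were cut out. Libraries were made with Illumina's TruSeq small RNA kit, carried index tags, were pooled, and were read as 50-nt single-end reads. The deposited files list each distinct small RNA sequence (a tag) with its read count, unnormalised. Tags were 18 to 34 nt long, and no tag was listed more than 1 time in a library. The tool used to remove adapters, and any filter on genome matches or ribosomal RNA, is not given in the sources used here. The kit adds no molecular identifier, so intervals and detection floors cover counting error only.

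The labels call the 4 and 5 mm anthers premeiotic and the 6 and 8 mm anthers meiotic, which gave 2 libraries per stage. They give no meiotic stage for the 10 mm anthers, which entered only the trend with anther length. They do not say that libraries came from separate plants, so p-values measure only the spread between these samples. The groups, tests, lists of microRNA families, rule for named tags and most alternatives were fixed before the data were examined.

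Library size was the number of reads of 20 to 24 nt, and CPM values are reads per 1000000 of these reads. Size-class shares and shares of reads by their 5' nucleotide were computed per library, with 95% Wilson intervals for the size classes. Stages were compared by two-sided exact permutation tests of the library values. With 2 libraries per stage, the smallest p such a test can give is 0.333, so none of these tests could pass 0.05.

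No genome was used here. Reads were assigned to 31 microRNA families through 57 mature sequences written down beforehand. A family took tags of 19 to 23 nt that lay within 1 nt of the reference length and differed from it by at most 2 mismatches when aligned at the 5' end. A tag went to the family with the fewest mismatches, and ties between families were dropped. A copy with a shifted 5' end was counted only if it met this rule. Among the families named, the leading tag had 2 mismatches for miR171, miR397, miR2118 and miR2275. The same references reversed gave the background, which was 0 reads in 5 libraries and 1 read in the 10 mm library. The families were sorted into 4 lists: triggers of phased small interfering RNAs (phasiRNAs), silencing machinery, development, and nutrients and copper. Fragments of ribosomal RNA, transfer RNA and chloroplast RNA were counted through a separate short list of conserved sequences. It held 5.8S and 5S ribosomal RNA, the transfer RNAs of Asp, Ala and Gly, and chloroplast 16S, 4.5S, psbA and rbcL. Other structural RNAs were not counted, so these values are not the whole structural content. The alternative without structural RNA left out tags of these sequences only.

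Tags of 20 to 24 nt with at least 2 CPM in at least 2 libraries were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM normalisation and Benjamini-Hochberg adjustment over all tags at 0.05. One model compared the 2 meiotic with the 2 premeiotic libraries. The other fitted a slope per mm of anther length over 5 libraries. Family sums were tested in the same way with the library sizes and TMM factors of the tag models. Log2 values are given with a standard error (SE). For edgeR it was derived from the test, as the size of the log2 value divided by the square root of the F statistic. DESeq2 1.42.0 (Wald test) was the second tool.

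The edgeR model for the stages was tested on simulated data drawn from the means of all 52101 tested tags, with 100 tags changed 4-fold and 100 changed 16-fold. At a dispersion of 0.05 it recovered 92% of the 4-fold and 100% of the 16-fold changes. At a dispersion of 0.5 it recovered 0% and 3%. The common dispersion of the 4 real libraries was 1.98.

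Dicer products carry 3' overhangs of 2 nt. The duplex ratio of a library and length was the number of pairs of distinct tags (at least 2 reads each) whose complementary parts left such overhangs, divided by the mean number of pairs at the 4 neighbouring overlaps, 2 nt and 1 nt to each side. On simulated duplexes every planted pair was found.

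Phased small RNAs were searched in sequences assembled from the tags themselves. K-mers of 17 seen at least 20 times were joined into non-branching sequences of at least 100 nt. A sequence counted as phased when a hypergeometric test over registers passed an adjusted p of 0.05, at least 40% of the reads of that length lay in the register, and at least 4 in-register positions were occupied. A position counted as occupied with 10 reads, a minimum chosen after the tags had been seen. In simulations of 21-nt duplexes on loci of 420 nt, all 50 loci were called when given whole, with 0 false calls in 50 random loci. Phasing at 22 or 24 nt was not simulated, and the sequences of the main assembly were shorter (median 115 nt, longest 219 nt). These rates therefore do not measure performance on the assembled sequences. None of the 50 was rebuilt from in-register tags alone, and all 50 were rebuilt with 5 reads at every other position.

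For leaf, with 1 library, no test was made. A family or tag was set apart only when its leaf CPM lay at least 4-fold above the highest or below the lowest anther library. The families named are those at 10 CPM or more in a library, and always miR2118, miR482, miR2275, miR390, tasiARF (a conserved trans-acting siRNA) and miR403. The miR172, miR394, miR395, miR397 and miR408 families lay below 10 CPM in every library and were named after their values were seen. Named tags are those called in the stage comparison, and, per length, the tag with the highest mean anther CPM among tags without a leaf read and the highest leaf CPM among tags at least 10-fold above every anther library. Any other tag named was chosen after its values were seen.

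Alternatives covered the denominator, distinct tags in place of reads, leaving out the 100 most abundant tags of each library or structural RNA, 3 other normalisations, DESeq2, CPM minimums of 0.5 and 10, family matching with at most 1 or 0 mismatches, no filter on families, the log of anther length, read minimums and depth for duplexes, k-mer settings, an in-register share of 25%, and each library left out in turn. Merging tags with copies that lack the 5' base, 8 assemblies in which weaker branches were dropped, a trend with the lengths of the 4 and 5 mm libraries exchanged, and tag maxima scaled by TMM factors were added after the data had been seen. Other values were computed in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.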

Results

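Small RNAs were sequenced from lily leaf and from anthers of 5 lengths that span the entry into meiosis. The data are read counts of distinct tags in 6 libraries. The total was 27230597 reads for leaf, 35481182 for 4 mm, 32042346 for 5 mm, 32027642 for 6 mm, 32597356 for 8 mm and 33536901 for 10 mm. Of these, 21602106 to 29250147 reads per library were 20 to 24 nt long. Between 73.7% and 76.6% of the tags of a library were seen 1 time. The 4 and 5 mm libraries are the premeiotic pair, the 6 and 8 mm libraries the meiotic pair, and the 10 mm and leaf libraries stand alone. Each anther library has its own length, so no length has a replicate. The SD of a stage pair therefore holds the difference between its lengths as well as other variation. The stage model takes that difference as spread, while the trend model fits a change with length to it.

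The first comparison asked which small RNA size classes anthers held before and during meiosis. In plants, 21-nt small RNAs include most microRNAs and one class of phasiRNAs, and 24-nt small RNAs include heterochromatic siRNAs and a second class of anther phasiRNAs. The 24-nt class led in the 4, 6, 8 and 10 mm libraries, and the 21-nt class led in leaf and in the library labelled 5 mm. Among distinct tags the 24-nt class led in every library, also in leaf (33.001% against 20.9% at 21 nt) and at 5 mm (34.3% against 22.7%). Without the 100 most abundant tags it led in leaf (28.5% against 24.8%) but not at 5 mm (28.6% against 35.8%). The 24-nt share was 40.6% ± 20.6 (SD, n = 2) in premeiotic and 61.8% ± 3.70 (SD, n = 2) in meiotic anthers. The 21-nt share was 27.9% ± 16.8 (SD, n = 2) in premeiotic and 12.7% ± 1.70 (SD, n = 2) in meiotic anthers.

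The premeiotic pair was unlike within itself. The 24-nt class made 55.2% of the 20 to 24-nt reads at 4 mm (95% Wilson interval 55.20 to 55.24) and 26.1% at 5 mm (26.04 to 26.08). It made 64.5% at 6 mm, 59.2% at 8 mm, 52.0% at 10 mm and 10.4% in leaf. The 21-nt class made 16.002% at 4 mm, 39.8% at 5 mm, 11.5% at 6 mm, 13.9% at 8 mm, 17.96% at 10 mm and 45.6% in leaf. The 22-nt class, which holds the usual triggers of phasiRNAs, made 7.16%, 13.0%, 5.29%, 7.71% and 10.8% from 4 to 10 mm, and 25.8% in leaf.

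Meiotic minus premeiotic, the 24-nt share differed by 21.2 percentage points and the 21-nt share by −15.2 (two-sided exact permutation p = 0.333 for both, the smallest possible). The 22-nt share differed by −3.59 (two-sided exact permutation p = 0.667). The 21-nt and 22-nt differences were smaller than the SD of the premeiotic pair, and the 24-nt difference was about as large. Without the 5 mm library the 24-nt difference was 6.62 and the 21-nt difference −3.29, and without the 4 mm library they were 35.8 and −27.1. The 22-nt difference was −0.657 without 5 mm and −6.52 without 4 mm.

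**Figure D1:**
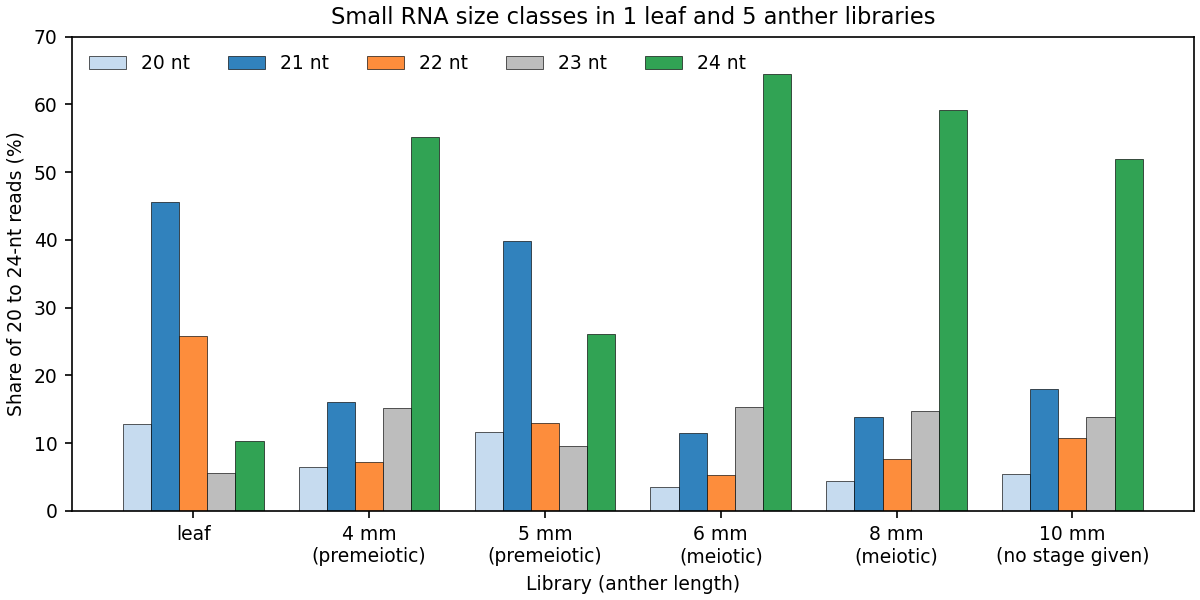
Share of 20 to 24-nt reads (%) in each size class, with 1 bar per length and library. The 24-nt bar is the tallest of its library at 4, 6, 8 and 10 mm (52.0% to 64.5%), and the 21-nt bar in leaf (45.6%) and at 5 mm (39.8%).

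Anther 21-nt small RNAs differed from those of leaf in their first base, which in plants guides the choice of Argonaute protein. A 5' C began 33.9% to 42.8% of the 21-nt reads in the 5 anther libraries and 5.35% in leaf, where a 5' T began 78.8%. The leaf values rested on a few abundant tags: 1 miR166 tag that starts with T had 5968581 of the 9844162 21-nt leaf reads. Without the 100 most abundant tags of each library, a 5' C began 21.6% of the 21-nt reads in leaf and 38.6% to 43.3% in anthers, and a 5' T 46.5% in leaf and 29.5% to 31.96% in anthers. The anther 21-nt share with a 5' C was 42.0% ± 1.13 (SD, n = 2) before and 37.4% ± 1.11 (SD, n = 2) during meiosis, a difference of −4.62 points. Among distinct tags that difference was 0.295. The 24-nt reads began with A in 46.0% of reads at 5 mm and in 33.998% to 38.1% in the other libraries. They began with C in 14.4% at 5 mm, 16.998% in leaf and 24.98% to 25.6% in the other anther libraries. None of the 8 base shares could pass between the stages (lowest exact permutation p 0.333, adjusted over the 8 shares 0.667).

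Most 24-nt reads of the 4 and 6 mm anthers had a complementary partner at the offset of a Dicer duplex, and at full depth so did those of 8 mm. Shares are given of the reads in tags with at least 2 reads. A partner with 2-nt 3' overhangs was present for 70.7% of the 24-nt reads at 4 mm, 74.7% at 6 mm, 61.5% at 8 mm and 39.6% at 10 mm. It was present for 4.34% at 5 mm and 7.12% in leaf. These shares depended on depth. With libraries thinned to the smallest, they were 55.6%, 57.3%, 45.1% and 28.3% at 4, 6, 8 and 10 mm. At 5 mm the thinned share was 2.64%, and in leaf 7.12%. The 24-nt duplex ratio was 9.51, 8.45, 5.29 and 3.23 at 4, 6, 8 and 10 mm, against 1.27 at 5 mm and 1.26 in leaf. For 21-nt reads the share with a partner was highest at 5 mm (51.0%), stood at 25.5% to 33.7% in the other anther libraries, and was 3.89% in leaf. Thinned in the same way, it was 40.8% at 5 mm, 22.8% to 33.7% in the other anther libraries and 2.65% in leaf. The 21-nt duplex ratio was 1.56 to 2.19 in anthers and 1.20 in leaf.

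Between the stages, the 24-nt duplex ratio was 5.39 ± 5.83 (SD, n = 2) before and 6.87 ± 2.24 (SD, n = 2) during meiosis (two-sided exact permutation p = 1). The 21-nt ratio was 2.04 ± 0.213 (SD, n = 2) and 1.92 ± 0.195 (SD, n = 2), with an exact permutation p of 0.667. Neither difference exceeded the spread of the premeiotic pair, and both changed sign with 1 library left out. The 24-nt difference was −2.64 without 5 mm and −0.101 without 6 mm, and the 21-nt difference was 0.0330 without 4 mm and 0.0201 without 8 mm. The ratios also depended on depth and on the read minimum. With libraries thinned to the depth of the smallest, the 24-nt ratios were 26.1, 24.6, 15.5 and 8.75 at 4, 6, 8 and 10 mm, 1.31 at 5 mm and 1.26 in leaf, and the differences were 6.35 at 24 nt and −0.367 at 21 nt (two-sided exact permutation p = 1 and 0.333). With minimums of 1 and 5 reads the 24-nt difference was 0.660 and 3.58.

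**Figure D2:**
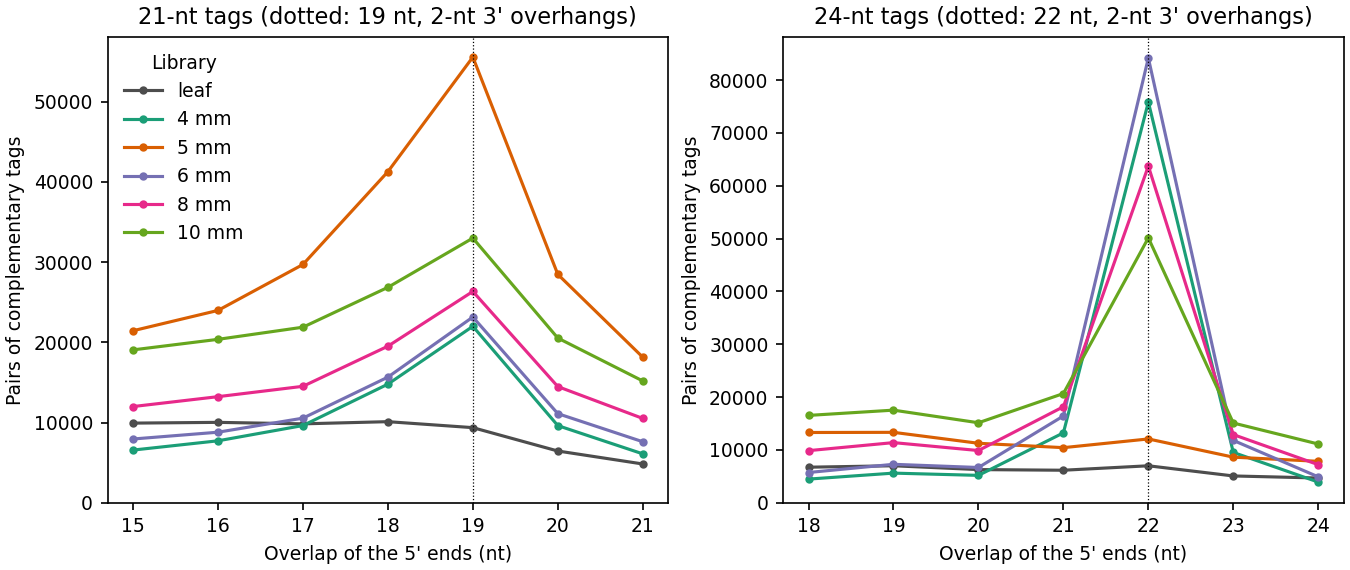
Number of pairs of complementary tags against the overlap of their 5' ends (nt), with 1 line per library, for 21-nt tags and 24-nt tags with at least 2 reads. At 24 nt, the 4, 6, 8 and 10 mm libraries peak at the overlap that leaves 2-nt 3' overhangs (ratios of 9.51, 8.45, 5.29 and 3.23 to the neighbouring overlaps), and the 5 mm and leaf lines are nearly flat (1.27 and 1.26).

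The second comparison asked which tags differed between premeiotic and meiotic anthers. Individual 24-nt tags followed the split within the premeiotic pair and not the stage. Of the 6660 24-nt tags at 10 CPM or more at 4 mm, 85.2% also reached 10 CPM at 6 mm and 12.3% at 5 mm. Of the 7032 such tags at 6 mm, 6.77% reached 10 CPM at 5 mm. The 21-nt tags did not follow that split. Of the 1824 at 10 CPM at 4 mm, 93.8% also reached 10 CPM at 5 mm and 52.7% to 56.5% at 6, 8 and 10 mm. Of the 3938 such tags at 5 mm, 43.4% reached it at 4 mm and 27.3% to 31.5% at 6, 8 and 10 mm. The 21-nt tags at 10 CPM at 6, 8 and 10 mm also reached it at 5 mm in 98.6%, 97.1% and 89.9%. Their CPM was higher at 5 mm, so these rates do not show that 4 and 5 mm are alike. Across 21-nt tags, the Pearson r of 4 mm was 0.782 with 5 mm, 0.829 with 6 mm and 0.833 with 8 mm.

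Among 4189 21-nt tags at 10 CPM or more in an anther library, 3529 had their highest CPM at 5 mm. That set holds more tags from 5 mm, where 3938 reached 10 CPM, than from any other library (1089 to 1824). Of 1267 such 22-nt tags, 663 were highest at 5 mm and 332 at 4 mm. Of 10177 such 24-nt tags, 2133 were highest at 4 mm, 2030 at 5 mm, 3234 at 6 mm, 1915 at 8 mm and 865 at 10 mm. These counts depend on the scaling. With CPM divided by the TMM factors of the trend model, an alternative chosen after the data had been seen, 1827 of the 21-nt tags, 190 of the 22-nt tags and 470 of the 24-nt tags were highest at 5 mm, and 1770, 702 and 2653 at 4 mm.

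In the edgeR model, 0 of 52101 tags passed the threshold between the stages, with 28 tags higher and 37 lower in meiotic anthers at an unadjusted p under 0.05. This test had little power. In simulated data at a dispersion of 0.5, below that of the real libraries, it recovered 3% of 16-fold changes. The 0 calls therefore do not show that tags were alike between the stages. Counts of 28 and 37 also lie below what evenly spread p-values would give. These unadjusted counts were 41 and 121 with DESeq2 size factors in edgeR, and 28 and 1 with totals of 20 to 24 nt. DESeq2 called 34 tags higher and 0 lower, of which 27 were 24 nt and 1 was 22 nt. Without the 4 mm library edgeR called 26967 tags higher and 2409 lower, and without the 5 mm library it called 0. The median log2 change of all tested tags was 0.47 with TMM factors, 1.14 with DESeq2 size factors and 0.15 with library totals, so a change below these shifts has no fixed direction.

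The most abundant anther tags without a leaf read differed in their course by length. At 21 nt, CGATTCATGAGCTCCGATCTC stood at 139 CPM at 5 mm and at 42.5 to 43.3 CPM in the other 4 anther libraries. At 22 nt, AGCTGGCCAGTATACCGAGGAC stood at 10.9 CPM at 4 mm, 112 at 5 mm and 27.9 to 28.8 from 6 to 10 mm. At 24 nt, GTATATACCATGTTTAGTCAGATT stood at 38.4 CPM at 4 mm, 0.157 at 5 mm (4 reads), 45.2 at 6 mm, 98.8 at 8 mm and 108 at 10 mm. The 4 reads at 5 mm cannot be told apart from reads assigned to the wrong library of the pool. The median abundant 24-nt tag had 0.0616% as many reads at 5 mm as in the 4, 6, 8 and 10 mm libraries together. For leaf, 0 reads allow up to 3 reads, or 0.139 CPM. The genes of these tags are not known here.

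The third comparison asked how microRNA families differed between the stages. No family of the 15 tested passed edgeR's threshold; 2 were higher and 0 lower at an unadjusted p under 0.05, and DESeq2 called 0. The largest of the 15 differences was that of miR390, which directs the tasiRNA pathway that restrains auxin response factors. Its log2 change was 1.91 ± 0.62 (SE), with an edgeR adjusted p of 0.0658 over all families and 0.00877 adjusted over the list alone. It stood at 9.40 CPM at 4 mm, 96.4 at 5 mm, 59.9 at 6 mm and 118 at 8 mm. The change rested on the 4 mm library. Without it the log2 change was 0.77 (edgeR adjusted p = 0.918), against 3.18 without 5 mm (0.0210), 1.94 without 6 mm (0.931) and 1.40 without 8 mm (0.998). With library totals in place of TMM it was 0.75.

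Of the list of phasiRNA and tasiRNA triggers, 2 of 5 members were abundant enough to test, and 1 passed when adjusted over the list alone. miR2275, the usual trigger of 24-nt phasiRNAs in grass anthers, stood at 29.4 ± 4.80 CPM (SD, n = 2) before and 10.99 ± 2.04 CPM (SD, n = 2) during meiosis. Its log2 change was −0.83 ± 0.59 (SE, edgeR adjusted p = 0.508), and it ranged from −1.28 (without 5 mm) to −0.62 (without 8 mm) with 1 library left out. With library totals it was −1.42, with DESeq2 size factors −0.38, and with at most 1 mismatch −1.30 (edgeR adjusted p = 0.0753, and 0.0143 over the list alone). The leading miR2275 tag differs from the references by 2 mismatches. miR2118, the usual trigger of 21-nt phasiRNAs, had 0 reads in all 5 anther libraries and 6 reads in leaf, and miR482 had 0 reads in all 6. At 0 reads the anther floor for miR2118 was 0.103 to 0.118 CPM per library. That floor covers counting error only. A lily miR2118 or miR482 with more than 2 mismatches to the references would not be counted, so 0 reads do not show absence. tasiARF reads reached at most 0.0690 CPM.

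None of the 2 silencing families tested passed, nor did the 9 developmental or the 2 nutrient families, also when adjusted over each list alone. miR167, which targets auxin response factors, had a log2 change of 1.42 ± 0.59 (SE, edgeR adjusted p = 0.173). With 1 library left out it ranged from 0.71 (without 8 mm) to 1.80 (without 6 mm), and with library totals it was 0.64. miR319, a regulator of TCP genes, stood at 525 CPM at 5 mm and at 92.1 to 195 CPM in the other anther libraries, with a log2 change of −0.05 ± 0.59 (SE). The miR396 change depended on the matching. It was 0.40 ± 0.58 (SE), and 1.65 ± 0.64 (SE) with at most 1 mismatch (edgeR adjusted p = 0.0753). Of the 15 families, 6 had the same direction under all 4 scalings, and miR390, miR167 and miR2275 were among them.

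Fragments of the listed ribosomal (5.8S and 5S), transfer and chloroplast RNAs were lower in both meiotic than in both premeiotic libraries. Ribosomal fragments stood at 5689 ± 276 CPM (SD, n = 2) before and 1787 ± 595 CPM (SD, n = 2) during meiosis (two-sided exact permutation p = 0.333, the smallest possible). The premeiotic mean was 3.18-fold the meiotic one for ribosomal, 2.95-fold for transfer and 4.54-fold for chloroplast fragments. The 4 and 5 mm libraries were close to each other in ribosomal fragments, at 5884 and 5494 CPM.

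The fourth comparison asked how families and tags changed with anther length over the 5 anther libraries. The 10 mm library held more of most conserved microRNAs than the 4 mm library, and less miR2275. By edgeR, 10 of 16 families rose and 1 fell, and 10 of these 11 passed when adjusted over the list alone. miR167 rose by 0.49 ± 0.07 (SE) log2 units per mm (edgeR adjusted p = 0.00187), from 87.8 CPM at 4 mm to 617 CPM at 10 mm. Its reads were 2503, 5304, 3905, 9242 and 18045 from 4 to 10 mm. The slopes are of TMM-scaled counts, and these unscaled values did not rise steadily. miR390 rose by 0.57 ± 0.12 (SE) per mm (edgeR adjusted p = 0.00681), from 9.40 to 160 CPM; without the 4 mm library the slope was 0.34 and passed.

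Of the 10 developmental families tested, 6 rose, among them miR166, which targets class III HD-ZIP genes (0.27 ± 0.05 per mm, SE, from 5401 to 17530 CPM), and miR172, which targets AP2-like genes (0.45 ± 0.09 per mm, SE). The others were miR156, miR167, miR171 and miR396. Unscaled values of miR166 did not rise steadily: its leading tag stood at 4588, 12875, 5514, 8322 and 15713 CPM from 4 to 10 mm. The miR166 slope leaves out a 21-nt tag that overlaps this one from an earlier 5' end. It stood at 3380, 6570, 2732, 3970 and 6885 CPM. Both nutrient families tested, miR398 and miR399, rose, and so did miR168 of the silencing list. miR2275 fell by 0.25 ± 0.08 (SE) log2 units per mm (edgeR adjusted p = 0.0303), from 25.97 CPM at 4 mm and 32.8 at 5 mm to 8.55 at 10 mm. The miR159, miR160, miR162, miR319 and miR394 families did not pass.

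The miR171 slope of 0.63 ± 0.09 (SE) rested on the tag TTGAGCCGCGCCAATATCACT, which differs from the references by 2 mismatches. That tag had 67 reads at 8 mm, 577 at 10 mm and at most 2 in each other library. With at most 1 mismatch the miR171 slope was 0.08, and it did not pass.

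All 11 called families kept their direction under 4 scalings, but their calls depended on the TMM factor, which was 2.21 at 5 mm and 0.776 to 0.878 elsewhere. With library totals in place of TMM, miR171 alone passed. The slopes of the 10 families that rose were then 0.17 to 0.51, against 0.25 to 0.63 with TMM, and that of miR2275 was −0.32, while the SEs of the 11 families were 0.15 to 0.21 against 0.05 to 0.12. Single libraries also ended calls. Without 4 mm, miR166 (slope 0.24), miR168 (0.21), miR172 (0.38), miR398 (0.29), miR399 (0.21) and miR2275 (−0.20) did not pass. Without 6 mm, miR156 (0.27), miR168 (0.29), miR390 (0.55), miR398 (0.29) and miR399 (0.30) did not. Without 8 mm, miR2275 (−0.24) did not. Without 10 mm, miR156 (0.07), miR166 (0.17), miR168 (0.33), miR171 (0.37), miR396 (0.13), miR398 (0.15), miR399 (0.20) and miR2275 (−0.36) did not. The count of families that rose was 5 without 4 mm or 6 mm and 3 without 10 mm. miR167 passed with each library left out. With DESeq2 size factors in edgeR, miR168 (0.26) and miR399 (0.29) did not pass, and with at most 1 mismatch, miR156 (0.25) and miR2275 (−0.22) did not. The DESeq2 Wald test called 9 families higher and 1 lower, and edgeR with the log of anther length also called 9 and 1. The miR396 slope was 0.25 ± 0.07 (SE), and 0.53 with at most 1 mismatch. Ribosomal fragments also differed with length, at 5884, 5494, 1367, 2208 and 2689 CPM from 4 to 10 mm. Among single tags, edgeR called 0 of 56877 for a trend, with 5592 positive and 589 negative slopes at an unadjusted p under 0.05, and DESeq2 called 620 and 167. The edgeR balance depended on scaling and filter. These unadjusted counts were 854 and 249 with DESeq2 size factors, 117 and 97 with totals of 20 to 24 nt, and 6730 and 12966 with a CPM minimum of 0.5.

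The fifth comparison set leaf beside the anthers. Conserved microRNAs made a far larger part of leaf than of anther small RNAs. The families made up 31.5% of the 20 to 24-nt reads in leaf and 0.586% to 1.91% in the anther libraries. These shares and the miR166 values leave out a 21-nt tag that overlaps the leading miR166 tag from an earlier 5' end. That tag stood at 2732 to 6885 CPM in anthers and 9616 CPM in leaf, so miR166 is undercounted, in anthers by a larger part. miR166 alone stood at 295184 CPM in leaf, through the tag TCGGACCAGGCTTCATTCCCC at 276296 CPM, and at 5401 to 17530 CPM in anthers.

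A further 6 families lay at least 4-fold higher in leaf than in any anther library. miR159, which targets GAMYB genes, stood at 3052 CPM in leaf and 11.2 to 35.9 in anthers. miR396, which targets growth-regulating factors, stood at 11055 CPM in leaf and 142 to 435 in anthers. Its leading tag made 191472 of the 238805 leaf reads, but 792 of 4570 reads at 4 mm and 7970 of 12737 at 10 mm. The rest came from other tags within the matching rule. miR398 of the copper response stood at 2926 CPM in leaf and 2.42 to 9.50 in anthers. Its anther reads were 1.74 to 6.99 times the 39.8 reads that 0.0629% of its leaf reads would give, the median share at which abundant anther 24-nt tags were seen in leaf. miR393 stood at 16.9 CPM and miR397 at 7.41 CPM in leaf, and both were below 1 CPM in every anther library. miR408 stood at 1.57 CPM in leaf and had 0 anther reads, which makes it at least 13.3-fold higher against a floor of 3 reads per library. For miR2118 the 6 leaf reads were at least 2.35-fold above that floor, short of the 4-fold bound.

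miR2275 went the other way, at 0.324 CPM in leaf (7 reads, 95% Poisson interval 0.130 to 0.668) and 8.55 to 32.8 CPM in anthers. miR395 had 0 reads in leaf and at most 0.410 CPM in anthers. miR319 stood at 37.5 CPM in leaf, below its lowest anther value of 92.1, within the 4-fold bound. miR390, miR160, miR171 and miR172 in leaf lay inside or near their anther ranges. miR162 (238 CPM in leaf), miR168 (53.0), miR156 (32.7), miR167 (2360) and miR399 (26.3) were above every anther library by less than 4-fold.

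**Figure D3:**
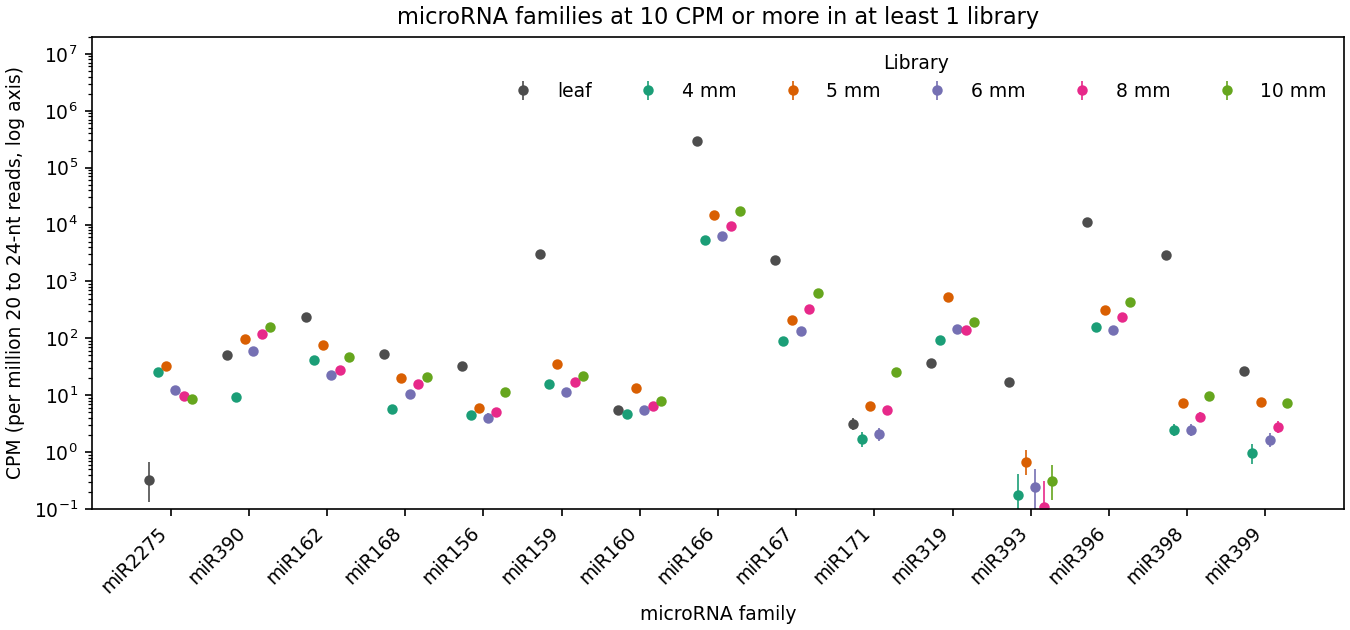
CPM on a log axis of the microRNA families at 10 CPM or more in at least 1 library, with 1 point per library and exact 95% Poisson intervals. miR166 stands at 295184 CPM in leaf and 5401 to 17530 CPM in anthers, and miR2275 at 0.324 CPM in leaf and 8.55 to 32.8 CPM in anthers. The miR166 points leave out the tag with an earlier 5' end.

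Most 21-nt and 24-nt anther tags were rare in leaf, and most 22-nt ones were not. Of the 10177 24-nt tags at 10 CPM or more in an anther library, 9341 were in leaf below 10% of their highest anther level. They held 36.8%, 6.20%, 45.6%, 39.3% and 29.4% of the 20 to 24-nt reads from 4 to 10 mm, and 0.240% in leaf. At 22 nt, 518 of 1267 tags lay below that level in leaf. At 21 nt, 3363 of 4189 did, and they held 20.9% of reads at 5 mm, 4.87% to 6.72% in the other anther libraries and 0.0509% in leaf. Among tags at 10 CPM or more in leaf, 438 of 927 at 21 nt, 215 of 691 at 22 nt and 255 of 702 at 24 nt lay at least 4-fold above every anther library. Among tags at least 10-fold above every anther library, the highest in leaf was AGTTACTAATTCATGATCTGGC at 22 nt, at 134386 CPM in leaf and 1944 to 6310 CPM in anthers, and at 24 nt CCACCCCAAGATGAGTGCTCTCCT, at 1308 CPM in leaf and 15.4 to 91.3 CPM in anthers. Chloroplast fragments stood at 195 CPM in leaf and 4.28 to 33.5 CPM in anthers.

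**Figure D4:**
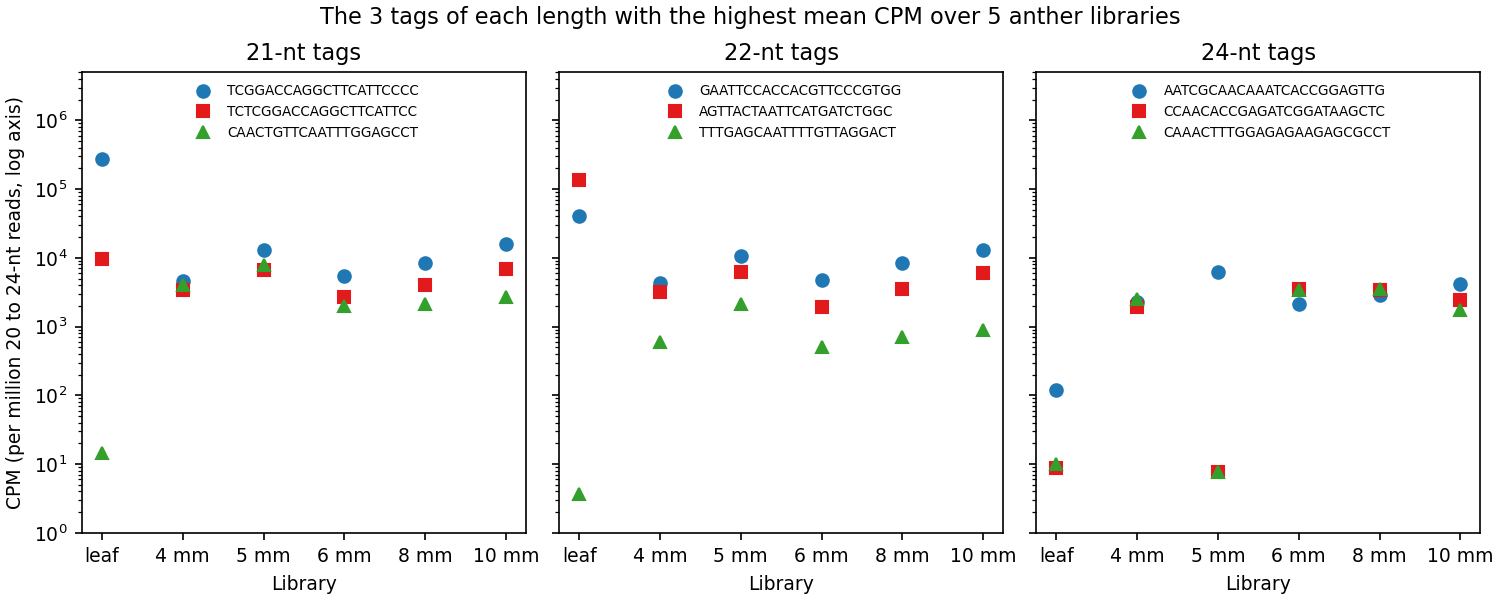
CPM on a log axis, in each library, of the 3 tags per length with the highest mean over the 5 anther libraries, chosen after their values were seen. CCAACACCGAGATCGGATAAGCTC and CAAACTTTGGAGAGAAGAGCGCCT stand at 1741 to 3483 CPM at 4, 6, 8 and 10 mm and below 10 CPM at 5 mm and in leaf. These low values cannot be told apart from reads assigned to the wrong library.

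The last comparison asked whether phased small RNAs could be found without a genome. No phased sequence was found at 21, 22 or 24 nt in the 4 planned assemblies. Of 8 assemblies chosen after the data had been seen, in which weaker branches were dropped, 4 gave 1 or 2 phased sequences at 21 nt (lowest adjusted p 0.00210) and none at 22 or 24 nt. The main assembly gave 44 sequences of at least 100 nt, with a median of 115 nt and a longest of 219 nt, and 0 of them passed the phasing test (lowest adjusted p of the hypergeometric test 0.0660, at 21 nt). Phased reads of that assembly were therefore 0 CPM in both stages. Sequences this short hold few cycles of 24 nt, and simulated loci were not rebuilt from in-register tags alone, so these counts of phased sequences do not measure the phasiRNA content of the anthers.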

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

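All tests in this part were chosen only after the values had been seen. Reads of 34 nt entered no comparison except as part of the totals of every length in 2 alternatives, and they held a signal of their own in all 6 libraries. They were 21.03 to 39.7 times as many as the 33-nt reads and made 1.56% to 2.45% of all reads. The start of the kit's 3' adapter, TGGAATTC, was present in 73.9% of the 34-nt reads of leaf, 66.4% at 4 mm, 72.9% at 5 mm, 67.1% at 6 mm, 70.2% at 8 mm and 71.8% at 10 mm. These values drew notice because they lie above the limit that a count of 0 allows (at most 0.000599% of the 34-nt reads of a library). The same bases in reversed order, CTTAAGGT, were present in 0.00990% to 0.0267% of the 34-nt reads, and the adapter start in 18.3% to 33.95% of the 33-nt reads. In 58.4% to 69.0% of the 34-nt reads, the sequence before the adapter start was itself a listed tag of 18 to 26 nt in the same library.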

How the results depend on the processing

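The alternatives added after seeing the data were the merging of 5'-truncated copies, the assemblies with weaker branches dropped, the trend with the 4 and 5 mm labels exchanged and the TMM scaling of tag maxima. Outside the runs that left out a library, 230 alternative values kept direction and call, but 33 of these belong to permutation tests that cannot pass and 127 are counts or values of 0 under both settings, which leaves 70. A further 24 moved, 13 lost their call, 1 gained one and 4 reversed. The 21-nt, 22-nt and 24-nt share differences kept their direction under every alternative run but not their size. Over the alternatives with all libraries they were 5.74 (distinct tags) to 25.4 (copies merged) points at 24 nt, −3.65 to −17.3 at 21 nt and −0.876 to −3.90 at 22 nt, with the same alternatives at both ends. Among distinct tags, the 21-nt first-base differences were 0.295 (5' C) and −2.73 (5' T), and the 24-nt 5' T difference was 0.155. Without the 100 most abundant tags, the 21-nt 5' T difference was −0.247. The cause was not tested for any of these.

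DESeq2 called 1 22-nt tag and 27 24-nt tags higher between the stages, and for the trend 143 higher and 107 lower at 21 nt, 152 and 11 at 22 nt, and 272 and 15 at 24 nt. Without a filter on family counts, 1 family (miR390) was higher between the stages. For the trend, 1 family was higher and 0 lower with totals of 20 to 24 nt and with totals of every length, and 0 were lower with up to 1 mismatch or with the 4 and 5 mm labels exchanged. With no mismatch 0 were lower because miR2275 was not among the 11 families tested. With weaker branches dropped, 2 sequences were phased at 21 nt with k-mer length 15 and minimum 20 (difference in phased reads −54.2 CPM), 2 with length 17 and minimum 3 (11.7 CPM), 1 with minimum 5 (10.3 CPM) and 2 with minimum 10 (−65.1 CPM). The other 4 such assemblies gave 0, and none gave a phased sequence at 22 or 24 nt.

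With each library left out in turn, the lone library of a stage was assumed to vary like the other group. The 21-nt duplex difference ranged from −0.269 to 0.0330 and the 24-nt one from −2.64 to 5.60. The 5' A difference at 21 nt ranged from −0.0556 to 2.61, and at 24 nt 5' C ranged from −0.355 to 10.8 and 5' T from −1.28 to 0.475. Called tags ranged from 0 to 185 higher and 0 to 1589 lower at 21 nt, 0 to 200 higher and 0 to 197 lower at 22 nt, and 0 to 19598 higher and 0 to 179 lower at 24 nt, all the high counts without the 4 mm library. Called families ranged from 0 to 1 higher between the stages, and from 3 to 10 higher and 0 to 1 lower for the trend. The miR319 stage change ranged from −0.98 to 0.59. No paired analysis was possible because the labels carry no replicate numbers. Depth limits families near the floor of 3 reads per library, 0.103 to 0.139 CPM.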

Other observations

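The tests in this part on read assignment, truncated copies and the 5 mm library, and the tags named in its first paragraph, were chosen only after the results had been seen. Several of the most abundant anther tags that no family counted differed in their course. Another such 21-nt tag overlaps the leading miR166 tag but has an earlier 5' end. It stood at 3380, 6570, 2732, 3970 and 6885 CPM from 4 to 10 mm and at 9616 CPM in leaf. Families were matched from the 5' end, so its reads are not in the miR166 values. The 24-nt tags CCAACACCGAGATCGGATAAGCTC and CAAACTTTGGAGAGAAGAGCGCCT stood at 1741 to 3483 CPM at 4, 6, 8 and 10 mm, at 7.55 and 7.67 CPM at 5 mm, and at 8.75 and 9.91 CPM in leaf. The 24-nt tag AATCGCAACAAATCACCGGAGTTG stood at 6233 CPM at 5 mm, 2139 to 4098 CPM in the other anther libraries and 121 CPM in leaf. The 21-nt tag CAACTGTTCAATTTGGAGCCT stood at 7804 CPM at 5 mm, 4040 at 4 mm, 1979 to 2687 from 6 to 10 mm and 14.6 in leaf. The 22-nt tag TTTGAGCAATTTTGTTAGGACT stood at 2151 CPM at 5 mm, 501 to 893 CPM in the other anther libraries and 3.70 in leaf. GAATTCCACCACGTTCCCGTGG, also 22 nt, was abundant in both tissues, at 40184 CPM in leaf and 4322, 10779, 4717, 8500 and 12971 CPM from 4 to 10 mm.

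Abundant anther tags differed in how many of them leaf shared. Of the 24-nt tags at 10 CPM or more, 12.6% of those at 5 mm also reached 10 CPM in leaf, against 1.45% to 4.79% of those in the other 4 anther libraries. This higher share goes with a smaller set at 5 mm, where 311 of 2459 tags were shared. The counts were 247 of 6660 at 4 mm, 102 of 7032 at 6 mm, 183 of 6122 at 8 mm and 252 of 5265 at 10 mm. For 21-nt tags the share was 9.88% at 5 mm and 14.6% to 22.5% in the other anther libraries. The lower 21-nt share goes with a larger set at 5 mm. The shared tags there were 389 of 3938, against 351 of 1824 at 4 mm and 159 of 1089 at 6 mm.

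The first pattern is the 5 mm library, which was out of line with the other anther libraries in its 24-nt RNA. If leaf RNA stood in place of anther RNA, 21 leaf-rich tags would stand near their leaf level. Their median of 0.212% argues against that. The 24-nt tags at 10 CPM at 4 mm had a median of 0.00311 of that level at 5 mm. An even loss of 24-nt RNA of that size is argued against by the 702 24-nt tags at 10 CPM in leaf. Their median was 1.98 times their level in the other anther libraries. That value is in CPM, which was higher at 5 mm for 21-nt tags too. The median 21-nt tag at 10 CPM at 4, 6, 8 or 10 mm stood there at 2.29 to 3.97 times its level. A smaller loss therefore stays open. By similarity over all tags the order with 4 and 5 mm exchanged ranked 3 of 60 and the label order 40, and over 24-nt tags they ranked 4 and 44. Neither was the shortest order there, which was 4, 6, 8, 10 and 5 mm for both sets of tags. Over 21-nt and 22-nt tags the label order ranked 1. An exchange of the 4 and 5 mm labels therefore cannot be told apart from a true difference. Such an exchange would leave the stage groups as they are; in the trend refitted with it, 9 families rose and 0 fell, the slope of miR390 was 0.45 and passed, and miR2275 (−0.22) and miR399 (0.28) did not pass. Anther length itself, and plants of another cultivar, stay open as untested explanations.

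The second pattern is the low level of most anther 24-nt tags in the leaf and 5 mm libraries. Over the 349 24-nt tags with at least 20000 reads in the 4, 6, 8 and 10 mm libraries together, the median tag had 0.0629% as many reads in leaf as in those libraries and 0.0616% at 5 mm, a ratio of 1.02. A few tags stood far higher, up to 53.0% in leaf and 54.8% at 5 mm, and over all 349 tags the reads came to 0.625% and 2.03%. RNA carried over from 1 anther library is argued against for the 341 tags in leaf and 337 at 5 mm that lay at or under 0.5%, since the highest part of 1 source library in a mixture fitted to them was 53.3% (bootstrap upper bound 62.1%). Reads assigned to the wrong library of a sequencing pool would give alike medians in leaf and at 5 mm, as seen. They should also come from every source library, but the part of the 8 mm library in the leaf mixture had a lower bound of 0. No test here separated such reads from low true levels, so the 2 cannot be told apart. At the median share in leaf, leaf reads would give 39.8 miR398 reads per anther library, against 69 at 4 mm, 70 at 6 mm and 278 at 10 mm.

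The third pattern is a copy without the 5' base beside abundant tags. In the 5 anther libraries the median copy had 19.03% to 19.8% as many reads as its 21-nt or 24-nt tag, a span of 0.817 points, and in 4 of them 60.9% to 73.1% of the 23-nt reads were such copies; leaf had a like median at 21 nt (19.1%) but 58.1% over its 10 abundant 24-nt tags. For these lengths, trimming in the anther that differs with stage, first base or length is argued against by a span of 2.14 points over libraries, lengths and first bases, and reads that start 1 base late, from library preparation or sequencing, are a candidate explanation that asks for such an even share, while uniform trimming stays open. At 22 nt the medians were uneven, at 90.4%, 56.1%, 26.2%, 25.8% and 30.0% from 4 to 10 mm, a span of 64.6 points. There, trimming that differs with anther length cannot be told apart from 21-nt RNAs with a level of their own, since only 6 to 19 tags per library were abundant enough and the quartiles at 4 mm (29.1% to 131%) and 8 mm (23.4% to 38.9%) overlap.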
